A study of Mus musculus with 14 samples.

How the data were processed

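RNA of 14 listed mouse samples was hybridised to Illumina Mouse-8 v2 expression arrays, 1 array per sample, per the labels. The deposited probe intensity is a signal on a linear scale, per the file headers, and its values show that background had not been subtracted. A detection p-value per probe and array was deposited beside it, per the file headers, and it is low for bright probes. The submitters' processing notes name BeadStudio 3.2, RMA and lumi without saying which step each performed. The series value table holds the authors' processed values on a log2 scale, where the base was inferred from the values; all 14 columns have the same quantiles, with a median of 4.23, and their ranks equal those of the matching intensity column. Their background correction is not given in the sources used here, and they served as an alternative.

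Intensities were corrected and normalized with limma 3.58.1 in R 4.3.3 (neqc: normexp with parameters inferred from the detection p-values, offset 16, quantile normalization, log2). Probes with a detection p under 0.01 on at least 2 of the 14 arrays were tested, 13034 of 25697. Of all probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were unlisted and stay unnamed here. The symbols of 23962 probes were matched through their Entrez identifiers to the RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. That table gave chromosome names only. All columns of per-sample values were used.

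Samples were grouped by the labels into GSC OG2, GSC OG2-ROSA, gPS OG2 and gPS OG2-ROSA (3 lines each) and ESC (2 arrays). A linear model of the 5 group means was fitted to all 14 arrays (lmFit and eBayes), and 9 contrasts were tested with Benjamini-Hochberg adjustment over the probes, calling an adjusted p under 0.05. All adjusted p values of genes come from limma. The series describes hybridisations as biological or technical duplicates without saying which. The 2 ESC arrays may therefore be technical replicates, yet the model counts them as 2 independent samples. The spread behind each p-value is shared by all 5 groups, so p-values against ESC may be too small. The number of arrays limits the precision. Where a probe was undetected on every array of a group, the fold is given as a lower bound: the bright group's mean against the mean, per dim array, of the higher of the lowest normalized signal among detected probes and the probe's own value. Log2 changes of such probes are fitted values, whose size depends on the background level.

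The design, the alternatives, 20 gene lists and the rule for named genes were fixed before the data were examined. The largest changes were taken, 12 per direction for the main comparison and 6 for the others, among genes called, detected on every array of a compared group and separated between all arrays of both sides. For the main comparison these genes also had to move the same way in both backgrounds. With them came up to 4 called members per list, those with the largest change whether separated or not, and 20 fixed genes, called or not. Placeholder symbols were passed over, and a gene with several probes was taken once, at the probe with the largest change, or in lists at the probe with the highest mean. Sohlh1 and Dnmt3l have several probes, so their values differ slightly between comparisons. The lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, in 5 of the comparisons.

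The procedure was tested on simulated data with 200 changed probes among 13034, using the real means and residual spreads. For the main comparison, 68.0% of changes of a log2 of 1 and 97.0% of changes of 2 were called. For gPS OG2 against ESC the shares were 22.0% and 84.0%, and for gPS OG2-ROSA against OG2 32.0% and 85.0%. Between 8 and 10 unchanged probes were called per simulated comparison. Simulated probes varied independently, and normalization was not rerun. With only 200 changed probes, the shares do not measure the sensitivity of the real main comparison, which called 8328. Alternatives covered background correction, scaling, probe filter, groups in the fit, the line number as a replicate block, array weights and leaving out each array. The array chip as a block was not run, since the columns name no chip. After the data were seen, further alternatives averaged the ESC arrays, left out both dim arrays, or took the fibroblast list mean as a covariate.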

Results

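Gene expression was measured on 14 mouse Illumina arrays of 25697 probes, 1 array per listed sample. The series text counts 13 samples and gives GSC OG2-ROSA line 2 in 2 replicates, whereas 14 samples with 1 array for that line are listed. Germline stem cells (GSC), cultured stem cells of the testis that the labels call unipotent, were represented by 3 lines carrying an Oct4-GFP reporter (OG2) and 3 lines carrying Oct4-GFP together with a LacZ transgene (OG2-ROSA). Pluripotent lines derived from germline stem cells (gPS) were likewise represented by 3 OG2 and 3 OG2-ROSA lines, and embryonic stem cells (ESC) by 2 arrays. The strain label was C57BL6 for the OG2 lines and ESC and a C57BL6 and 129sv cross for OG2-ROSA, so strain and transgene cannot be told apart. The titles of the OG2 and ESC samples carry a replicate mark that the OG2-ROSA titles lack, so a batch cannot be told apart from the background either. Mean signal was 614 to 639.5 on the GSC arrays, 622 and 584 on the ESC arrays and 513 to 579.9 on the gPS arrays, except 379 and 308 on those of gPS OG2-ROSA lines 1 and 2. Every GSC array was brighter than every gPS array (mean 628 ± 10.3 against 481 ± 111, SD, n = 6 each, exact two-sided permutation p = 0.00216). The mean signal was 3.67 to 4.96 times the estimated mean of the negative controls, lowest on gPS OG2-ROSA line 2. Between 9638 and 11610 probes were detected per array. GSC arrays detected 11332 ± 274 probes and gPS arrays 9960 ± 306 (mean ± SD, n = 6 each), with an exact two-sided permutation p of 0.00216, the smallest that the 924 splits can give.

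**Figure D1:**
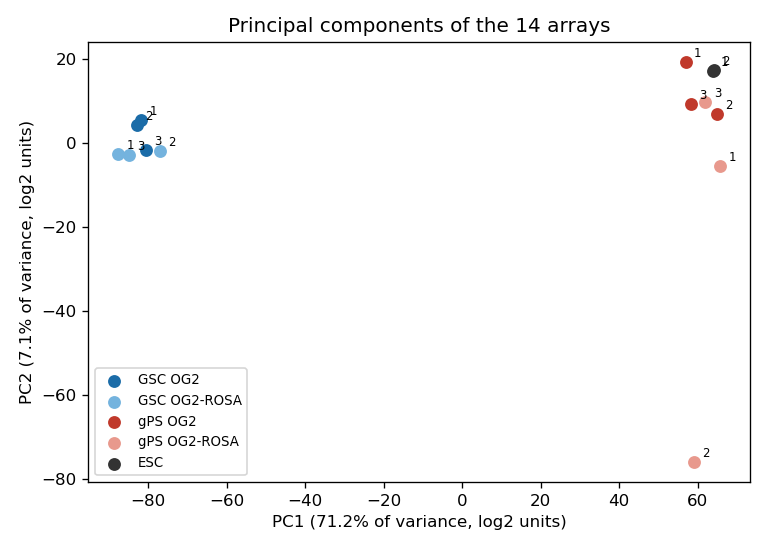
Principal components of the 14 arrays over the tested probes, with PC1 on the x axis and PC2 on the y axis, both in log2 units. Each point is 1 array, coloured by group and numbered by line or replicate; PC1 (71.2% of the variance) parted GSC from gPS and ESC, and PC2 (7.06%) was most extreme on gPS OG2-ROSA line 2.

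The first question was how close each cell type stood to the others. Across genes, gPS and ESC arrays correlated with a mean Pearson r of 0.958 (range 0.921 to 0.979 over 12 pairs of arrays), whereas gPS and GSC arrays correlated with a mean r of 0.797 (0.771 to 0.818 over 36 pairs). ESC and GSC arrays gave 0.801 (0.792 to 0.814). Within groups, r was 0.960 to 0.975 in GSC OG2, 0.967 to 0.983 in GSC OG2-ROSA and 0.927 to 0.953 in gPS OG2-ROSA, and its mean over the 3 pairs was 0.964 in gPS OG2. The ESC pair reached 0.992. These are correlations across genes, which are not independent replicates, and no test was attached to them. Of the gPS lines, OG2-ROSA line 3 stood nearest to the ESC mean (r = 0.981) and OG2-ROSA line 2 farthest (0.924).

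The main comparison set the pluripotent lines against the germline stem cells, averaged over both backgrounds. Germline genes were lower in the gPS lines. Sohlh1, a transcription factor of spermatogonia, was undetected on all 6 gPS arrays and at least 80.2-fold lower (log2 change -7.19; n = 6 arrays each). Egr4, a zinc finger transcription factor, and Dazl, an RNA-binding protein of germ cells, had log2 changes of -7.78 (SE 0.39) and -7.02 (SE 0.28). Egr4 was detected on only 2 and Dazl on only 1 of the 6 gPS arrays, so the size of these changes depends on the background level. In the other direction, L1td1 was at least 115-fold higher in gPS (log2 change 7.66, SE 0.15) and Nanog, a core pluripotency transcription factor, at least 69.2-fold higher (log2 change 6.70, SE 0.15), since neither was detected on any GSC array. Dnmt3l, a cofactor of DNA methyltransferases, rose from a log2 intensity of 6.83 to 13.82.

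The other genes with the largest increases were Trh, Lefty2, Gtsf1l, Gdf3, Cldn4, Mylpf, Slc7a3, Bcat1 and Lefty1, with log2 changes from 5.85 (Lefty1) to 7.42 (Trh). Lefty2, Gtsf1l and Cldn4 were detected on no GSC array, and were at least 66.0-fold, 34.6-fold and 43.3-fold higher. Lefty1, Lefty2 and Gdf3 encode ligands of the TGF-beta family, and Bcat1 and Slc7a3 act in amino acid metabolism and transport. The largest decreases besides these were in Xlr4a, Taf7l, Mageb4, Tuba3a, Lyz1, Ifi27, Nlrp4c, Taf9b and Asz1, the last with a log2 change of -6.22. Of these, Xlr4a, Taf7l, Mageb4 and Taf9b lie on the X chromosome, as does Slc7a3 among the increases. The share of X-linked probes among all tested probes was not computed. By the rule that picked them, all genes named so far as changed had all 6 gPS arrays on 1 side of all 6 GSC arrays, and moved the same way in both backgrounds. Their limma adjusted p values lay between 1.69e-12 for L1td1 and 4.35e-07 for Lyz1.

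**Figure D2:**
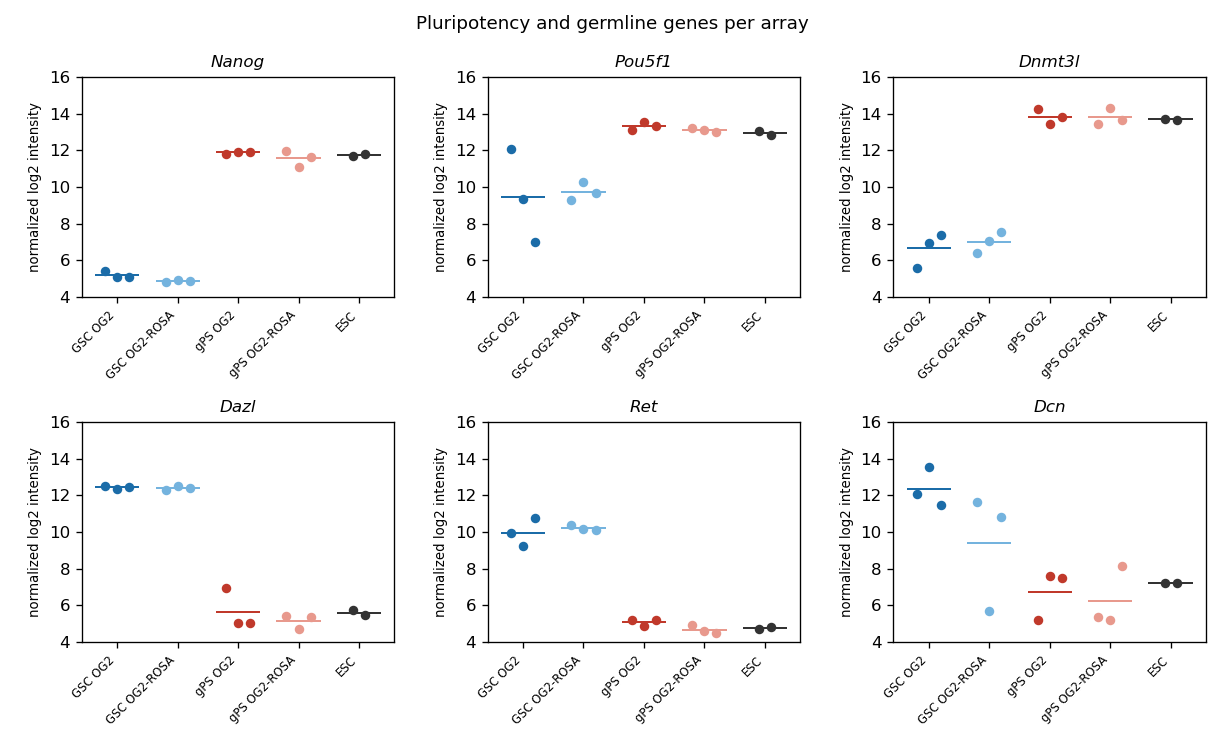
Normalized log2 intensity (y axis) of 6 genes on each array, by group (x axis). Points are single arrays and horizontal lines are group means; Nanog and Dnmt3l were high in gPS and ESC, Dazl and Ret were high in GSC, and Dcn was low on GSC OG2-ROSA line 2, at 5.68 against 10.84 to 13.58 on the other GSC arrays.

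Of all tested probes, 63.9% were called in this comparison, 47.6% of the calls being higher, and the counts by list below should be read against these shares. The pluripotency network rose as a group. Of its 34 tested members, 31 rose, 1 fell and 2 did not pass the test, with the same 31 and 1 when adjusted over the list alone, and the list was called higher by camera (adjusted p = 3.54e-13; adjusted p = 0.00143 with an estimated correlation). Pou5f1 rose by a log2 of 3.61 (SE 0.59), Sox2 by 3.88 (SE 0.41), Esrrb by 5.11 (SE 0.22), Zfp42 by 2.49 (SE 0.19) and Dppa5a by 4.05 (SE 0.15). Pou5f1 was already detected on all 6 GSC arrays, at 7.02 to 12.07 (log2 intensity, mean 9.61), highest on GSC OG2 line 1, and its rise was 4.29 without that line and 3.02 without GSC OG2 line 3. Klf4 and Myc, which belong with Pou5f1 and Sox2 to the factors used to induce pluripotency, rose by a log2 of 1.35 and by at least 1.95-fold, Myc being detected on no GSC array. Dppa3 rose by 2.24 (adjusted p = 0.0164), but was undetected on 1 of the 6 gPS arrays. Sall4 rose by 0.53, and Lin28a changed by 0.46 (95% interval -0.20 to 1.11) without passing the test, while another probe of Lin28a was called, at 0.84 (adjusted p = 0.00119). Without gPS OG2-ROSA line 2, the dimmest array, the first of these changes was 0.79 and passed the limma test.

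Genes of spermatogonial stem and progenitor cells mostly fell. Of 37 tested members, 25 fell, 6 rose and 6 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000561; adjusted p = 0.0354 with an estimated correlation). Ret, the receptor subunit for GDNF signalling, was undetected on all 6 gPS arrays and had a log2 change of -5.21 (SE 0.21), Ddx4 of -4.32 (SE 0.26), Stra8 of -3.17 (SE 0.52) and Bcl6b of -1.32 (SE 0.39). The Bcl6b values of GSC and gPS arrays overlapped, and its call was lost with the fibroblast list mean as a covariate. Etv5 rose by 2.11 (SE 0.38) and Utf1 by 5.31 (SE 0.33). Gfra1, the GDNF co-receptor, stood near the detection limit, with a log2 change of -0.19 (95% interval -0.73 to 0.35; 0.12 with median scaling) that did not pass. Zbtb16 and Kit were not analysed here.

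The germ granule and meiotic lists moved the same way. Of 19 tested genes of the piRNA pathway, which silences transposons in germ cells, 16 fell and 1 rose, or 17 and 1 adjusted over the list alone. Tdrkh, undetected on all gPS arrays, was at least 35.1-fold lower and Asz1 had a log2 change of -6.22, while Dnmt3l, counted in this list too, was the member that rose. Camera called the list lower (adjusted p = 1.43e-07), a call lost at adjusted p = 0.112 with an estimated correlation. Of 18 meiosis genes 13 fell and 2 rose, with the same counts adjusted over the list alone (adjusted p = 0.000308; adjusted p = 0.0189 with an estimated correlation), among them the cohesin subunits Smc1b at -6.18 and Stag3 at -4.74. Of 6 postmeiotic spermatid genes 4 fell and 1 rose, also over the list alone, without a call for the list (camera adjusted p = 0.284). Among those that fell were Ldhc (-2.81) and Izumo1 (undetected on all gPS arrays, fitted log2 change -2.26). The Ldhc values overlapped, with gPS OG2 line 1 at 8.97 against 8.11 to 9.71 on the GSC arrays.

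Of 17 tested glycolysis genes 14 rose and 3 fell, also adjusted over the list alone, and the largest increases were in Pfkl (3.54 on the log2 scale, SE 0.21), Ldha (3.01, SE 0.21), Pfkp (3.00, SE 0.45) and the glucose transporter Slc2a3 (2.76, SE 0.23). The call for the list (camera adjusted p = 0.000115) was lost at adjusted p = 0.32 with an estimated correlation. Of 28 cell cycle genes 15 rose and 7 fell, also over the list alone (adjusted p = 0.132). The cyclin gene Ccne1 rose by 4.05, and the cyclin gene Ccnd2 and the cycle inhibitors Cdkn2a and Rb1 had log2 changes of -4.10, -3.49 and -2.20. Of 16 genes of DNA methylation and TET enzymes, 9 rose and 4 fell, also over the list alone (adjusted p = 0.121), with Tdg at 2.18 and Gadd45a at 1.87. Of 20 signalling targets of GDNF, FGF and LIF, 9 rose and 4 fell, also over the list alone (adjusted p = 0.144), with Socs2 at 4.34 and Dusp4 at 3.46.

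Imprinted genes went both ways. Of 16 tested paternally expressed genes 8 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.28). Snrpn rose by a log2 of 4.37 (SE 0.13) and Ddc by 3.70 (SE 0.18), whereas Dlk1 had a change of -4.08 (SE 0.45) and Igf2 of -3.24 (SE 0.32). Within GSC, Dlk1 and Igf2 were lowest on OG2-ROSA line 2 (7.49 against 9.75 to 11.5, and 12.86 against 13.41 to 14.6). The fibroblast list mean was lowest on that array too, and which cells gave these signals was not tested. Of 14 maternally expressed genes 2 rose and 5 fell, also over the list alone (adjusted p = 0.526), with Cdkn1c at -2.19 and Phlda2 at 1.59. Dcn, counted here and among the fibroblast genes, fell by 4.38.

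Primed epiblast genes rose in 7 and fell in 2 of 13 cases, also adjusted over the list alone, led by Cldn6, at least 21.5-fold higher, and Nodal, at least 8.99-fold higher. That list's call (camera adjusted p = 0.0434) was lost at adjusted p = 0.32 with an estimated correlation, and without GSC OG2 line 3 (adjusted p = 0.0531) or gPS OG2-ROSA line 2 (0.0718). Counts adjusted over the list alone equalled those over all probes in each list that follows. Of 12 trophoblast genes 6 rose and 1 fell (adjusted p = 0.144; Tfap2c 2.67, Dlx3 -1.77). Neuroectoderm genes split into 4 up and 4 down of 9 (adjusted p = 0.851; Gbx2 5.40, Zic1 at least 20.2-fold lower), and mesoderm genes into 3 up and 4 down of 13 (adjusted p = 0.929; Bmp4 4.14, Foxf1 at least 9.40-fold lower). Extraembryonic endoderm genes gave 5 up and 6 down of 15 (adjusted p = 0.971; Apoe 3.63, Pdgfra -3.21). Of 4 tested genes of the 2-cell-like state 3 rose (adjusted p = 0.225; Eif1a 1.41, and Zscan4c with a fitted change of 1.96). Zscan4c lay below the detection level on the GSC arrays (4.61 to 4.69). It was detected on only 2 of the 6 gPS arrays, gPS OG2 lines 1 and 3 (9.72 and 8.06).

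Of 29 tested fibroblast genes, 5 of which stand in another list too, 16 fell and 3 rose from GSC to gPS, also adjusted over the list alone (camera adjusted p = 0.0932). Dcn had a log2 change of -4.38 (SE 0.91), Pdgfra of -3.21 (SE 0.40) and Col3a1 of -2.58 (SE 0.60). The mean log2 intensity of this list was 8.84 ± 0.92 in GSC and 7.74 ± 0.58 in gPS (SD, n = 6 each; exact two-sided permutation p = 0.0368), and only 7.15 on GSC OG2-ROSA line 2. Among 11 genes of Sertoli, Leydig and peritubular cells 5 rose and 3 fell, also over the list alone (adjusted p = 0.579), with Rhox5 at 3.67 and Wt1 at -2.82. Of 6 tested Y-linked genes and Xist, 4 fell, also over the list alone (adjusted p = 0.0616). Usp9y was at least 9.67-fold lower, and the fitted log2 changes were -3.43 for Eif2s3y, -2.09 for Kdm5d and -0.97 for Zfy1. Of the 6 gPS arrays, Eif2s3y was detected on 3, Kdm5d on 1 and Zfy1 on 0. Zfy1 lay at 5.78 to 6.25 in GSC, about where detection began on the gPS arrays (5.96 to 6.22), so the size of its fall is unknown. Eif2s3y lay between 10.06 and 10.55 on the GSC arrays but between 4.57 and 10.39 on the gPS arrays.

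In total, 8328 of 13034 tested probes passed the test in limma (adjusted p under 0.05), 3965 higher and 4363 lower in gPS, and 4287 of them changed at least 2-fold. The latter count depended on the background correction and was 2815 with normexp at offset 50 and 2217 with no correction. With arrays scaled by their medians instead of their quantiles, the median log2 change of all probes was 0.15 rather than -0.04, and the higher share of the calls was 57.9% rather than 47.6%. The same scaling moved that share from 47.0% to 57.7% in OG2 alone and from 47.6% to 59.4% in OG2-ROSA alone.

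Each background was then taken alone. In OG2, L1td1 (at least 139-fold), Dnmt3l, Trh, Nanog, Mylpf and Lefty2 led the genes higher in gPS, with log2 changes from 7.88 to 6.49, and Egr4, Mageb4, Tuba3a, Sohlh1, Taf7l and Dazl led those lower, from -7.74 to -6.77. Nanog and Lefty2 were undetected in GSC OG2 and Sohlh1 in gPS OG2 (at least 81.0-fold, 56.4-fold and 88.4-fold). In OG2-ROSA, Trh (at least 160.2-fold), L1td1, Lefty2, Dnmt3l, Nanog and Gtsf1l led the increases, from 7.75 to 6.29, and Xlr4a, Egr4, Dazl, Taf7l, Sohlh1 and Nlrp4c the decreases, from -8.17 to -7.00. All named increases but Dnmt3l were undetected in GSC OG2-ROSA, and all named decreases but Egr4 in gPS OG2-ROSA, with bounds from 35.5-fold (Gtsf1l) and 52.5-fold (Nlrp4c) upwards. The limma test called 6441 probes in OG2 (3030 higher, 3411 lower) and 6532 in OG2-ROSA (3111 higher, 3421 lower), with 3 arrays per group. Of these, 2450 were higher and 2727 lower in both, against 723 and 895 for independent lists, and 1 was called in opposite directions. The log2 changes correlated across probes with r = 0.924, and the 2 comparisons shared no arrays. They did share the normalization and the spread per probe, so the lists were not independent and part of the overlap can come from that. Of the calls, 4200 in OG2 and 4314 in OG2-ROSA were at least 2-fold, or 2184 and 2311 with no background correction. With the fibroblast list mean as a covariate, 3691 probes were called in OG2.

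The test of the difference between the backgrounds called 1 probe, that of Olig1, a transcription factor of the oligodendrocyte lineage. It rose by a log2 of 5.88 from GSC to gPS in OG2-ROSA against a log2 change of -0.57 in OG2 that did not pass, a fitted difference of 6.45 (SE 0.43, limma adjusted p = 1.52e-05). Olig1 was detected on no GSC array and on no gPS OG2 array, so the size of this difference depends on the background level. At an unadjusted p under 0.05 there were 653 probes. The count was 12 without gPS OG2-ROSA line 3, 9 without GSC OG2 line 3, and 3, 2, 3 and 2 without gPS OG2-ROSA line 1 or 2 and gPS OG2 line 2 or 1.

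Embryonic stem cells gave the reference for pluripotency, and the reference distance was that from GSC OG2. The largest differences higher in GSC OG2 than in ESC were those of Mageb4 (at least 141-fold), Egr4, Tuba3a, Taf7l, Sohlh1 and Dazl, all undetected in ESC, with fitted log2 differences from 8.51 to 6.83. Trh, Lefty2, Dnmt3l, Krt42, L1td1 and Nanog were lower, from -7.52 to -6.57 (Lefty2, Krt42, L1td1 and Nanog undetected in GSC OG2), as were Sox2 by -3.66 and Zfp42 by -3.02. Pou5f1 differed by -3.50, by -4.83 without GSC OG2 line 1, by -2.28 without line 3, and by -3.37 without ESC array 1, where it was not called (adjusted p = 0.0538), nor was it with only the groups compared (adjusted p = 0.0659) or the fibroblast list mean as a covariate (adjusted p = 0.115). With that covariate the Sox2 difference was not called either. The limma test called 5962 probes, 3127 higher and 2835 lower in GSC, and 4280 at least 2-fold, or 2298 with no background correction and 2801 with the fibroblast list mean as a covariate. These calls went the way of the conversion in OG2-ROSA, which shares no array with them, in 98.2% of cases. Of the probes higher in ESC, 2312 were also called higher in gPS OG2-ROSA than in GSC OG2-ROSA, and of those lower 2522 were called lower, against 677 and 821 for independent lists. Both comparisons used the same spread per probe, so their lists were not independent. The count of probes called between GSC OG2 and ESC was 3906 and 3868 with 1 ESC array left out. It was 3803 with both arrays averaged and 2851 with the fibroblast list mean as a covariate. Median scaling moved the share called higher in GSC OG2 from 52.4% to 42.2%.

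The gPS OG2 lines were set against ESC next. Slc4a3 was at least 22.3-fold higher (log2 difference 4.82, SE 0.39), Nod1, a sensor of bacterial peptidoglycan, at least 15.3-fold higher (4.73, SE 0.34), and Obsl1 at least 6.05-fold, Pou3f1 at least 5.64-fold, Nnat at least 2.38-fold and Gbp2 at least 2.17-fold higher. Thumpd1 was at least 26.4-fold and Olig1 at least 21.5-fold lower, Mff at least 9.42-fold, Tdgf1 at least 8.60-fold, Pmel at least 7.87-fold and Trim59 at least 7.82-fold, all undetected on the gPS OG2 arrays. Pou5f1 differed by 0.38 (95% interval -1.63 to 2.39), Nanog by 0.14 (-0.36 to 0.64), Sox2 by -0.09 (-1.48 to 1.30) and Zfp42 by -0.55 (-1.18 to 0.09), and none of these passed the test. The intervals use 1 spread per probe, shared by all 5 groups. For Pou5f1 the SD was 2.53 in GSC OG2 but 0.21 in gPS OG2 and 0.15 in ESC, so the GSC lines widened its interval. With only the groups compared it was not called either (limma adjusted p = 0.479). The probe of Tdgf1 that was lower is a second probe of that gene, whose brightest probe was not called.

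By list, 0 of 34 pluripotency genes were called against ESC in gPS OG2, and 1 adjusted over the list alone (camera adjusted p = 0.815). Camera called 4 lists higher in gPS OG2 than in ESC: mesoderm and primed epiblast (adjusted p = 0.000305 each), paternally expressed imprinted genes (0.000305) and trophoblast (0.00106). All were lost with an estimated correlation, at adjusted p = 0.135 for the first 3 and adjusted p = 0.179 for trophoblast. No mesoderm gene was called (0 of 13 by limma, 2 adjusted over the list alone), and the mean of that list was high on gPS OG2 lines 2 and 3 (6.70 and 6.83) but 5.77 on line 1, against 5.63 and 5.64 in ESC. The called members of the other lists were Fgf5 (at least 1.32-fold) and Pou3f1 for primed epiblast, Nnat and Peg10 (log2 difference 1.63) for imprinted genes, and Cdx2 (at least 1.65-fold) for trophoblast. Among maternally expressed genes Grb10 differed by -2.72 (SE 0.54). The germline genes Tex14 and Stag3 were 3.53-fold and 4.01-fold lower. Altogether 109 probes were called by limma, 42 higher and 67 lower, and 1302 had an unadjusted p under 0.05. With the ESC arrays averaged and counted as 1 sample, 10 were called, with array weights 1634 and without both dim arrays 247. The count was 17 and 10 without ESC array 1 or 2, 50 without gPS OG2 line 3, 70 without GSC OG2-ROSA line 3 and 164 without gPS OG2-ROSA line 2.

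The gPS OG2-ROSA lines were compared with ESC in the same way. Nod1 (at least 10.1-fold), Slc4a3, Glrx, Obsl1, Nnat and Fez1 were higher, with log2 differences from 4.12 to 2.38, and Pmel, Grb10, Nanos3, Gramd4, Fgfr1op2 and Tmem40 were lower, from -3.24 to -2.17. Slc4a3, Obsl1 and Nnat were undetected in ESC (at least 9.61-fold, 2.30-fold and 1.84-fold higher). Nanos3, an RNA-binding factor of germ cells, and Gramd4 were undetected on all 3 gPS OG2-ROSA arrays and at least 3.63-fold and 2.69-fold lower. Pou5f1 differed by 0.13 (95% interval -1.88 to 2.14), Nanog by -0.18 (-0.68 to 0.32), Sox2 by 0.27 (-1.13 to 1.66) and Zfp42 by 0.04 (-0.60 to 0.68). These intervals use the shared spread too, which for Pou5f1 was larger in GSC OG2 (SD 2.53) than in gPS OG2-ROSA (0.11). No pluripotency gene was called, 0 of 34 also over the list alone (camera adjusted p = 0.53). Only the cell cycle list was called, higher in gPS OG2-ROSA (adjusted p = 0.0437; adjusted p = 0.52 with an estimated correlation), with 0 of its 28 members called. That call was also lost without gPS OG2-ROSA line 3 (adjusted p = 0.141), GSC OG2 line 1 (0.0569) or gPS OG2 line 2 (0.0537). In all 34 probes were called by limma, 15 higher and 19 lower, and 1278 had an unadjusted p under 0.05. The count was 261 without gPS OG2-ROSA line 3, 22 without line 2, 16 without both dim arrays (lines 1 and 2) and 3 with the ESC arrays averaged. It was 2 and 5 without ESC array 1 or 2, and 22 without GSC OG2-ROSA line 1 or 3. Median scaling moved the share called higher from 44.1% to 56.5%.

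**Figure D3:**
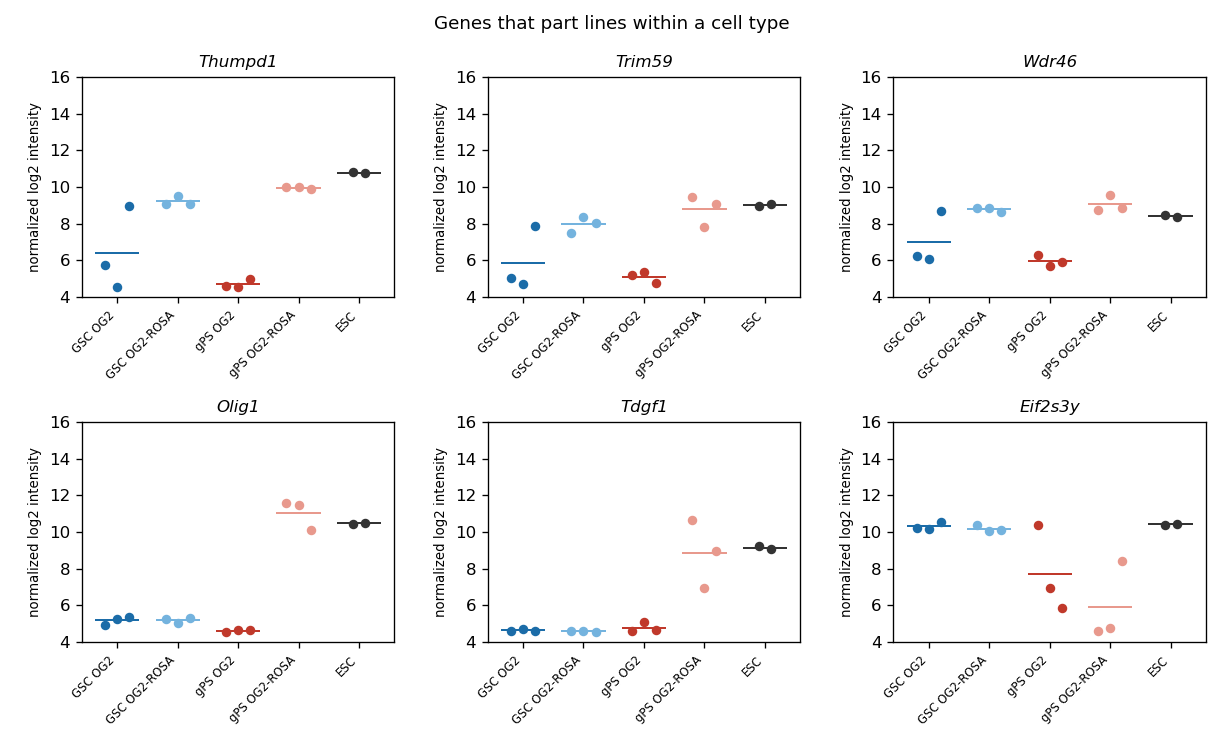
Normalized log2 intensity (y axis) of 6 genes on each array, by group (x axis). Points are single arrays and horizontal lines are group means; Thumpd1, Trim59 and Wdr46 were low in gPS OG2 and on GSC OG2 lines 1 and 2, Olig1 and the Tdgf1 probe shown were low in gPS OG2 and in GSC, and Eif2s3y ranged from 4.57 to 10.39 among the gPS lines.

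Between the backgrounds, gPS OG2-ROSA lines stood above gPS OG2 lines in Olig1 (at least 32.1-fold), Thumpd1 (fitted log2 difference 5.26, SE 0.75), Tdgf1 (at least 6.95-fold), Trim59 (at least 6.62-fold) and Ubd (at least 3.42-fold), each undetected on the gPS OG2 arrays, and in Wdr46 (log2 difference 3.12). The other probe of Tdgf1 differed by -0.66 and was not called (adjusted p = 0.69). The gPS OG2-ROSA lines stood below in Id2, an inhibitor of helix-loop-helix factors (-2.24, SE 0.38), in Tmem254a (-1.24) and Vamp8 (-1.15), and in Igdcc3 and Ift122, at least 1.98-fold and 1.66-fold, and Krt23 (fitted log2 difference -1.70), which were undetected on the gPS OG2-ROSA arrays. Camera called trophoblast (adjusted p = 0.000219) and mesoderm genes (adjusted p = 0.0417) lower in gPS OG2-ROSA, with 0 members called, or 3 and 4 adjusted over the list alone, and both calls were lost with an estimated correlation, at adjusted p = 0.336 and adjusted p = 0.6. The mesoderm mean of gPS OG2 line 1 (5.77) did not exceed that of any gPS OG2-ROSA line (5.77 to 6.01), so that difference came from gPS OG2 lines 2 and 3. Its call was lost without gPS OG2 line 2 or 3 (adjusted p = 0.0653 and 0.279), gPS OG2-ROSA line 2 or 3 (0.0954 and 0.17) or GSC OG2-ROSA line 1 (0.0548). The limma test called 29 probes, 23 higher and 6 lower in OG2-ROSA, and 1393 had an unadjusted p under 0.05. The count was 220 without gPS OG2-ROSA line 3 and 46 without GSC OG2 line 3. It was 7 to 17 without any 1 of the GSC OG2-ROSA lines, the ESC arrays, gPS OG2 lines 1 and 3, or gPS OG2-ROSA lines 1 and 2, and 11 without both dim arrays.

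In germline stem cells the backgrounds differed in 1 probe, that of Cstdc4, higher in OG2-ROSA by a log2 of 1.62 (SE 0.20, limma adjusted p = 0.0196). The fibroblast list was called lower in GSC OG2-ROSA (camera adjusted p = 1.86e-17), a call lost at adjusted p = 0.397 with an estimated correlation, with 0 of 29 members called and 1 adjusted over the list alone. Its mean was 9.10 to 9.71 in GSC OG2 and 9.04, 7.15 and 8.54 in GSC OG2-ROSA, and without line 2 of the latter the adjusted p was 6.81e-06. At an unadjusted p under 0.05 there were 510 probes. The limma count was 82 without GSC OG2 line 3 and 0 with the authors' processed values. It was 0 without any 1 of GSC OG2 lines 1 and 2, the GSC OG2-ROSA lines, the ESC arrays or gPS OG2 line 3, with 303 to 511 probes at an unadjusted p under 0.05.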

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

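The limma comparisons and the counts over other splits were planned, and the tests of dim arrays, of single probes, of an inherited strain difference and of the origin of GSC OG2 line 3 were chosen after the results were seen.

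Olig1 stood out because its change from GSC to gPS differed between the backgrounds by a log2 of 6.45 (SE 0.43), by the test of the difference itself. Its log2 intensity was 4.53 to 4.66 in gPS OG2, 10.12 to 11.56 in gPS OG2-ROSA, 10.46 and 10.50 in ESC, and 4.93 to 5.34 in GSC. For the count of 1 called probe chance cannot be excluded, since 31 of 100 splits of the 12 GSC and gPS arrays gave as many, and the highest other split gave 20.

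For gPS against GSC over both backgrounds chance is unlikely: 1 of 100 splits, the real one, gave as many as 8328 probes. This is the smallest share that 100 splits can give, and the highest other split gave 2992. Within OG2 (6441) and within OG2-ROSA (6532) the 10 splits are too few for a share under 0.05, and the highest other split gave 0 probes by limma in both. They are also too few for the backgrounds in GSC (1 probe, highest other 14, 4 of 10 splits as large) and in gPS (29 probes, highest other 45, 2 of 10). The split with 14 probes exchanges GSC OG2 line 3 and GSC OG2-ROSA line 2.

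Of the 29 probes apart between the gPS lines of the backgrounds, 13 were detected on every array of a GSC group, and at 12 of these (92.3%) the GSC difference had the same sign. None of the 12 was called in GSC (0 by limma, 5 at an unadjusted p under 0.05), and their differences ranged in size from 0.04 to 2.79. An inherited strain difference may account for that, but ESC, which carry the strain label of OG2, lay closer to gPS OG2-ROSA at 25 of the 29 probes, so this stays open. Dim gPS OG2-ROSA arrays as a cause were not decided by the GSC lines. Their median difference in the same direction was 0.39, between the bounds set, and genes may differ in gPS alone. Without both dim arrays all 29 probes kept their direction, with a median difference of 1.46 (median SE 0.28) rather than 1.70 (0.25). That fit leaves line 3 alone in its group, assumed to vary like the other groups. This line was not dim, but the 29 probes were picked from a comparison that included it and the same gPS OG2 arrays. Their kept direction was thus largely fixed in advance and does not decide on dim signal, and 1 array decides little. Sequence differences under single probes stay open (median of 10 other probes of 8 of the genes 0.76). Of the 10, 5 differed by over 1 in the same direction. The other 5 differed by under 0.25 in that direction, among them the Tdgf1 probe, which went the opposite way (-0.66). At 12 of the 13 probes (92.3%) GSC OG2 line 3 lay closer to the GSC OG2-ROSA mean than to the other GSC OG2 lines, against 1 of 13 for lines 1 and 2 each. A candidate explanation is that this line has another origin than its label, a hypothesis found and tested on the same data, and the labels were kept as given.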

How the results depend on the processing

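All alternatives were planned except the averaged ESC arrays, the left-out dim arrays and the fibroblast covariate, chosen after seeing the data. Where results moved, the cause was not tested, except that fewer arrays leave fewer degrees of freedom. The chip as a block was not run. Line numbers did not pair GSC with gPS lines (correlations of lines of the same number -0.160 to 0.0039), so the replicate block is an alternative only. Signal over the negative controls, 3.67 on the dimmest array, limits what weak probes can show.

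Counts of called probes for gPS against GSC stayed within 1.5 times the reported ones under all alternatives, except 3691 in OG2 with the fibroblast covariate. Counts at least 2-fold moved further, from 4287 to 2815 with normexp offset 50 and to 2217 with no background correction, which also gave 2184 in OG2 and 2311 in OG2-ROSA. Of the genes named for the mean of both backgrounds, 2713 values kept side and direction over the alternatives, 9 lost the call, 3 gained it and 1 reversed. Bcl6b, Dcn, Col3a1 and Etv4 lost it with the fibroblast covariate, and Bcl6b also without the dim arrays. Dcn and Col3a1 belong to the list whose mean is that covariate, so their loss of the call says little. For gPS OG2 against ESC, 96 lost the call, for gPS OG2-ROSA against ESC 85, for gPS OG2-ROSA against OG2 121 and for GSC OG2 against ESC 4. In that order, 474, 326, 191 and 386 values kept side and direction. Cstdc4, the only gene named for GSC OG2-ROSA against OG2, lost the call in 16 alternatives and kept it in 10.

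GSC OG2-ROSA against OG2 gave 0 calls by limma with normexp offset 50, no background correction, the authors' values, only the groups compared, the replicate block, ESC averaged, the dim arrays left out and the fibroblast covariate, and 8 with array weights. gPS OG2-ROSA against OG2 gave 19 with no background correction, 19 with median scaling, 16 with the authors' values, 7 with only the groups compared, 9 with the replicate block, 9 with array weights, 8 with ESC averaged and 11 without the dim arrays. gPS OG2 against ESC gave 69 with the authors' values, 68 with only the groups compared, 1634 with array weights, 10 with ESC averaged and 247 without the dim arrays. gPS OG2-ROSA against ESC gave 2 with only the groups compared, 19 with the replicate block, 3 with ESC averaged and 16 without the dim arrays. GSC OG2 against ESC gave 3803 with ESC averaged and 2851 with the covariate. The difference between backgrounds gave 3 with array weights and 5 without the dim arrays.

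Camera called 6, 4, 1, 1 and 2 lists for gPS against GSC, gPS OG2 and OG2-ROSA against ESC, and the backgrounds in GSC and gPS. With an estimated correlation it called 3, 0, 0, 0 and 0, and fry 18, 0, 0, 0 and 0. In GSC, normexp offset 50 gave 2 lists. For gPS OG2-ROSA against ESC, the authors' values and the replicate block gave 0. The mean r of gPS with GSC, 0.797, was 0.828 with no background correction, 0.762 with the authors' values and 0.896 with no filter.

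None of the called genes named in the text reversed, and the other called probes were not followed singly. Of uncalled genes, Gfra1 turned to 0.124 and Zfp42 (gPS OG2-ROSA against ESC) to -0.002 with median scaling. Sox2 in gPS OG2 against ESC turned to 0.006 with the replicate block and 0.192 with the covariate. In gPS OG2-ROSA against ESC, Sox2 turned to -0.235 and Zfp42 to -0.05 without the dim arrays, Zfp42 ranged from -0.057 without ESC array 2 to 0.139 without ESC array 1, and Nanog from -0.382 without gPS OG2-ROSA line 1 to 0.047 without line 2.

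With each array left out in turn, calls ranged from 7834 to 8563 for gPS against GSC, 5502 to 7068 in OG2 and 5548 to 6636 in OG2-ROSA, 1 to 12 for the difference, 10 to 164 for gPS OG2 against ESC, 2 to 261 for gPS OG2-ROSA against ESC, 3868 to 6589 for GSC OG2 against ESC, 0 to 82 for the backgrounds in GSC and 7 to 220 in gPS. A lone ESC array is assumed to vary like the other groups. Lists ranged from 5 to 8, 4 to 7, 0 to 3, 1 to 3 and 1 to 2 in the order above.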

Other observations

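The limma comparisons and the test of dim arrays for Eif2s3y were planned, and those of a strain variant, of Y loss and of the sources of the fibroblast list were chosen after the result was seen.

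Among further genes of the fixed lists in gPS against GSC (limma, n = 6 each), Otx2 was at least 5.87-fold and En2 at least 2.71-fold higher. The laminin genes Lama1 and Lamc1 rose by a log2 of 3.03 (SE 0.41) and 2.42 (SE 0.27), and the FGF-responsive transcription factor Etv4 by 2.59 (SE 0.57). Etv1, another of these, was detected on no GSC array and was at least 3.33-fold higher. The keratin gene Krt8 rose by 2.18 and Tead4 by 1.77. The germ cell gene Tex11 was undetected on all gPS arrays, with a fitted log2 change of -5.87, Tex101 was at least 12.5-fold lower, and the Sertoli cell tight junction gene Cldn11 at least 2.30-fold lower. The receptor tyrosine kinase gene Axl had a log2 change of -1.83 (SE 0.35), and Pou3f1 of -1.47 (SE 0.34).

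Eif2s3y was 10.06 to 10.55 on the GSC arrays and 10.40 and 10.44 in ESC, but 10.39, 6.94 and 5.84 in gPS OG2 and 4.57, 4.77 and 8.44 in gPS OG2-ROSA. Dim arrays are argued against, as 0% of 1081 autosomal probes of like ESC level fell as far, and so is a strain variant at the probe, as GSC differed from ESC by only -0.17. Loss of the Y chromosome from part of the cells stays open: over the 6 gPS arrays Eif2s3y followed the mean of 5 other Y-linked probes (Spearman rho 0.943, exact permutation p = 0.0167; Pearson r 0.965, exact permutation p = 0.00417). Adjusted over the 2 relations computed, the p values were 0.0333 (Spearman, permutation) and 0.00833 (Pearson, permutation), and r was 0.904 without gPS OG2 line 1 and gPS OG2-ROSA line 3. This test decides little, since of the 5 probes only Uty and Kdm5d were detected on any gPS array. Uty, near the detection limit, was 6.67, 6.41 and 6.12 in gPS OG2, 6.01, 6.08 and 6.21 in gPS OG2-ROSA and 5.74 to 6.68 in GSC, and Usp9y, Kdm5d and Zfy1 were undetected in ESC too.

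The mean of the fibroblast list was lower in gPS than in GSC, but camera did not call the list (adjusted p = 0.0932). Its genes moved together over the 6 GSC arrays, with a mean pairwise correlation of 0.501, at percentile 100 of 10000 random lists (highest 0.171). Random lists were matched on mean expression only, so co-regulated genes could exceed them whichever cells express them. The list mean was 7.15 on GSC OG2-ROSA line 2 against 8.54 to 9.71 on the other GSC arrays. The correlation was not computed without that line, and it does not tell the 2 sources below apart. RNA of feeder fibroblasts on the GSC arrays is a candidate explanation, as a hypothesis. Some abundant members were low together on GSC OG2-ROSA line 2: Bgn was 9.27 against 11.94 to 12.95 on the others, and Igfbp7 8.35 against 10.17 to 11.75. Timp1 was little lower there (9.32 against 9.59 to 11.86), and Col1a2, Vim, S100a4 and Twist1 did not have their lowest GSC value there. Expression by the germline stem cells themselves stays open: the list mean did not follow that of the spermatogonial list (Pearson r -0.481, exact permutation p = 0.267; Spearman rho -0.60, exact permutation p = 0.242; r -0.207 without the 2 farthest arrays). The spermatogonial list varied little there (SD 0.161 against 0.921), so 6 arrays decide little.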
